A study of Mus musculus with 4 samples.

How the data were processed

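Total RNA was isolated with Trizol from gastrocnemius muscles pooled over 10 mice per group and hybridized to 4 MG-U74Av2 arrays, 1 per group, per the labels. The deposited values were linear probe set intensity signals that the authors computed from the scanned images with MAS 5.0, per the labels. In the deposited columns the trimmed mean over all probe sets, with 2% left out at each end, was 500 on the intact, adrenalectomized and 24 h arrays and 500.6 on the 3 h array, so the authors had scaled each array to that target. The labels state that no replicate was made. The instrument settings that came with the arrays gave 1 chip lot, 1 hybridization day, 1 scan day and fluidics modules 1, 2, 3 and 4 in the order intact, adrenalectomized, 3 h and 24 h. Settings of the scaling other than the target were not given in the sources used here.

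The table held 12488 probe sets, of which 66 were controls. On the 3 h array 20 control probe sets had no value, and no other value was missing. Each array was scaled so that the trimmed mean of the 12422 other probe sets was 500, signals below a floor of 100 were set to the floor, and log2 ratios were taken. Gene symbols came from the platform's own annotation: 10833 probe sets had 1 symbol, 396 had several and 1193 had none. Of the 10833, 10817 matched the gene table of the GRCm38.p6 assembly by gene ID, which was used for names only and changed 0 symbols. Each of the 8251 genes was represented by its probe set with the highest mean signal, and 2073 genes had more than 1 probe set. The probe set of 1045 genes carried a suffix that marks probes shared with other transcripts or chosen under relaxed rules. Among genes named below, Igkv6-23, Mup3, Serpina1b, Serpina1e, Myh7, Atp2a2, Krt27 and Cd22 had only such probe sets. The same held for Lsm2, Mettl18, Snrp1c-ps2, Med27, Zfp36 and Krtdap, and other named genes may belong here too. The signals of such genes may include other transcripts.

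Median signals were 189, 197, 194 and 199.6 in the order of the groups. The 3'/5' ratios were 0.88, 0.89, 0.88 and 0.83 for Gapdh and 1.10, 1.07, 1.04 and 1.04 for actin. The correlation of log2 signals between arrays lay between 0.968 for 24 h and 3 h and 0.985 for intact and adrenalectomized. The spike-in control BioDn-3 read 658, 220, 416 and 211. The other BioB, BioC, BioDn and CreX spike-in controls that had a value read at most 78.7 on any array.

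The 3 main comparisons were adrenalectomized against intact, 3 h against adrenalectomized and 24 h against adrenalectomized, and the 3 secondary ones were 24 h against 3 h, 24 h against intact and 3 h against intact. With 1 array per group no test, p-value or standard error was computed. A gene was counted when its log2 ratio was at least 1 in size (2-fold), and where the dimmer array was below the floor the fold is given as a lower bound. The only error measure within the data was the SD of the difference in log2 ratio between 2 probe sets of the same gene. This SD was divided by the square root of 2 and is given in the report. Both sets were read at or above the floor on the same arrays, so it holds no variation between mice, pools or dissections. Of the genes past 2-fold by their brighter set, the other set had the same sign for 3 of 4, 15 of 17 and 5 of 6 genes in the main comparisons and passed 1.5-fold the same way for 1, 8 and 2 of them. In 24 h against 3 h, 24 h against intact and 3 h against intact the sign was the same for 15 of 20, 5 of 10 and 16 of 17 genes. The correlation of log2 ratios between the sets across genes was 0.16, 0.35 and 0.11 in the main comparisons.

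The comparisons, the size rule, 28 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists were glucocorticoid-induced genes, muscle atrophy and autophagy, proteasome subunits, circadian clock, inflammatory mediators, interferon response and antigen presentation, immediate early genes, heat shock proteins, fatty acid uptake and oxidation, glycolysis and glycogen, oxidative phosphorylation, amino acid metabolism, polyamine synthesis, cholesterol and fatty acid synthesis, insulin-like growth factor and myogenic regulation, glucocorticoid receptor and steroid metabolism, ribosomal proteins, extracellular matrix, fast fibre genes, slow fibre genes, and markers of adipocytes, B and T lymphocytes, neutrophils, macrophages, endothelium, Schwann cells and nerve, erythroid cells, and satellite cells and smooth muscle. Another 3 lists, of epidermis and hair follicle markers, hepatocyte markers and soleus-enriched genes outside the slow fibre list, were added after the data had been seen. A list was described by the median log2 ratio of its members at or above the floor on at least 1 array of the comparison, by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, and by counts of members past 1.5-fold and 2-fold. At least 5 members were needed. The percentiles describe these arrays and are not p-values.

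Genes were named by a fixed rule. In each main comparison these were the 8 highest and 8 lowest genes past 2-fold that were measured on both arrays and had no other probe set of the opposite sign, and the 3 highest and 3 lowest bounds. In each secondary comparison they were the 4 highest and 4 lowest. Up to 4 members of each list with the largest log2 ratio in size were added, and always Fkbp5, Tsc22d3, Per1, Mt1, Mt2, Glul, Pdk4, Cebpd, Sgk1, Cdkn1a, Nr3c1 and Mstn. Fbxo32 and Trim63 belonged to the rule but had no probe set with a single symbol. Genes named outside the rule were chosen after their values were seen: they are list members beyond the 4 of their list and comparison, and genes followed across all 4 arrays.

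For comparisons that share an array, 100 simulations of unchanged arrays gave the correlation, covariance and overlap expected without any effect. The calculation was tested on simulated data built from the 8251 genes for 3 h against adrenalectomized. Its noise was set from adrenalectomized against intact, the most alike pair of arrays. The number of unchanged genes that passed may therefore be too low, and the shares given next rest on that noise. There 2% of 50 genes with a true fold of 1.5 passed 2-fold, 38% at a true fold of 2, 86% at 3 and 88% at 5, and 8 of 5914 unchanged genes passed. A simulated list of 15 genes shifted by 0.5 was found at 0.56 with a percentile of 100, and 2 of 40 unshifted lists lay outside the central 95%.

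Alternatives were the deposited values without further scaling, median scaling, quantile normalization, loess against the mean array with a span of 0.4, scaling to ribosomal protein probe sets, floors of 50 and 200, log2 of the signal plus 32 in place of a floor, the mean of all probe sets of a gene, and no probe sets of shared probes. The ribosomal scaling used the geometric mean of all ribosomal protein probe sets, those below the floor included. Size rules of 1.5-fold and 3-fold were applied to the counts, and random lists without matching to the percentiles. Probe sets with no single gene symbol were left out of all comparisons. The computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.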

Results

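Messenger RNA of mouse gastrocnemius, a calf muscle made mostly of fast fibres, was measured on 4 Affymetrix MG-U74Av2 oligonucleotide arrays. Each array carried RNA pooled from 10 mice, and each of the 4 groups had 1 array. The groups were intact mice, adrenalectomized mice, and adrenalectomized mice taken 3 h or 24 h after an intraperitoneal injection of 0.1 mg of cortisol. Adrenalectomy removes the gland that makes corticosterone, the main glucocorticoid of the mouse, and cortisol acts on the same receptor. The interval of 1 week after surgery was given for the adrenalectomized group alone. The labels named no group injected with vehicle and no time of day. Signals at or above the floor of 100 were found for 63.0% of the probe sets on the intact array, 63.0% on the adrenalectomized array, 63.4% on the 3 h array and 64.4% on the 24 h array. With 1 array per group the differences had no replicate check, the number of arrays limited the precision, and each comparison set 1 pool against another. The arrays were also processed in 4 different fluidics modules, so group, pool and module cannot be told apart. Of 8251 genes, 6416 reached the floor on at least 1 array. The SD of the error of a log2 ratio, estimated from genes with a second probe set, was 0.24 for adrenalectomized against intact, 0.28 for 3 h against adrenalectomized and 0.32 for 24 h against adrenalectomized.

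The comparison of adrenalectomized with intact mice asked what the loss of adrenal hormones did to muscle transcripts. Fkbp5, which encodes a chaperone that restrains the glucocorticoid receptor and is itself induced by glucocorticoids, was lower without adrenals. Cebpd, a transcription factor gene of the same class of targets, was higher. The medians of the extracellular matrix list and of the erythroid list were higher. The medians of the fat cell, polyamine synthesis and lymphocyte lists were negative, by small amounts and with some members higher.

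Among 6112 genes compared, 21 were at least 2-fold higher and 23 at least 2-fold lower after adrenalectomy, 0.720% in all. Without the members of the epidermis, hepatocyte, slow fibre, fast fibre and lymphocyte lists the counts were 21 higher and 21 lower. When the arrays were scaled to ribosomal protein probe sets, 38 genes were higher and 19 lower, with the median of all genes at 0.13 on the log2 scale. Of the 44 genes, 28 were measured above the floor on both arrays, and 23 of these 28 had a mean signal under 300. Pmm1, an enzyme gene of mannose metabolism, had signals of 284 after adrenalectomy and 101 in intact mice, a 2.80-fold difference. Stmn1, a regulator of microtubules, was 2.79-fold higher, the nicotinic receptor gene Chrna7 was 2.57-fold higher and the transcription factor gene Lef1 was 2.47-fold higher. Pdc (2.68-fold), Mettl18 (2.43-fold), Pimreg (2.43-fold) and Larp7 (2.28-fold) completed the 8 measured genes named as highest. Trh was at least 2.48-fold higher, Lsm2 at least 2.44-fold and Degs2 at least 2.30-fold, since their intact signals were below the floor. Camk2a, a calcium-dependent kinase gene, was 3.69-fold lower, with 149.6 against 552. Tex2 was 3.40-fold lower, Oxt 3.31-fold, Snrp1c-ps2 2.79-fold and the actin-binding protein gene Dbnl 2.73-fold. Dynll2, a dynein light chain gene, stood out among the lower genes by brightness, with signals of 1961 and 5031, but its log2 ratio was -0.72 when all its probe sets were averaged. Psg19 was 2.47-fold lower and Icmt 2.44-fold lower. The immunoglobulin gene Igkv6-23 was at least 4.11-fold lower, Otog at least 3.82-fold and Hcrt at least 3.08-fold.

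Glucocorticoid-induced genes had a median log2 ratio of -0.04 over 27 members, near the all-gene median, and the sign turned positive under scaling to ribosomal protein probe sets. No member passed 2-fold. Fkbp5 read 1349 in intact mice and 796 after adrenalectomy, which is 1.70-fold lower, while Cebpd was 1.61-fold higher and Tsc22d3, a glucocorticoid-induced leucine zipper gene, was 1.45-fold higher. Mt1, Mt2, Per1, Sgk1, Cdkn1a, Pdk4, Glul, Mstn and the receptor gene Nr3c1 each differed by less than 1.5-fold.

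Extracellular matrix genes had a median of 0.17 over 30 members, above the matched random lists (percentile 100). The 3 members past 1.5-fold were Col4a2 at 1.69-fold, Col4a1 at 1.55-fold and the crosslinking enzyme gene Lox at 1.53-fold higher. The lowest member had a log2 ratio of -0.48. Macrophage markers had a median of 0.20 over 13 members (percentile 98.8), with Tyrobp 1.58-fold higher. Erythroid markers had a median of 0.53 over 5 members (percentile 99.9); Alas2 was 1.85-fold higher, Hbb-b2 1.46-fold and Hba-a1 1.24-fold. Slow fibre genes had a median of 0.14 over 12 members and fast fibre genes one of 0.03 over 15. Both lay above the central 95% of random lists matched on expression and inside it when the random lists were not matched. Adipocyte markers had a median of -0.26 over 9 members (percentile 0.27) with none past 1.5-fold, and Adipoq, Retn and Lipe were each 1.37-fold lower. Polyamine synthesis genes had a median of -0.22 over 5 members (percentile 1.05) with none past 1.5-fold, and with the rate-limiting enzyme gene Odc1 1.30-fold lower. B and T lymphocyte markers had a median of -0.20 over 8 members (percentile 1.68), with Cd4 2.10-fold and Cd79a 2.02-fold lower and the other 6 within 1.5-fold. Fatty acid uptake and oxidation genes had a median of -0.09 and oxidative phosphorylation genes one of -0.06, both below the central 95%, and both became positive under scaling to ribosomal protein probe sets. Hepatocyte markers, a list added after the data were seen, had a median of -0.44 over 22 members. Albumin, the main product of liver cells, read 956 on the intact array and 686 after adrenalectomy.

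The remaining lists lay inside the central 95% of matched random lists in adrenalectomized against intact mice. Their medians were 0.14 for endothelial markers, 0.11 for Schwann cell and nerve markers, 0.07 for inflammatory mediators (negative with a floor of 200) and 0.04 for circadian clock genes. Medians of 0.02 were found for proteasome subunits and for interferon response and antigen presentation genes. Muscle atrophy and autophagy genes, glycolysis and glycogen genes, ribosomal proteins and amino acid metabolism genes had medians within 0.01 of 0. Satellite and smooth muscle markers, neutrophil markers and cholesterol and fatty acid synthesis genes each had a median of -0.02. The medians were -0.04 for insulin-like growth factor and myogenic regulation genes, -0.05 for immediate early genes, -0.08 for heat shock proteins and -0.10 for glucocorticoid receptor and steroid metabolism genes. The 2 added lists of epidermis and hair follicle markers and of soleus-enriched genes had medians of -0.04 and -0.09. The negative medians from -0.02 to -0.10 became positive under scaling to ribosomal protein probe sets, and those of proteasome subunits and of interferon response genes turned negative under median scaling. Of the 28 fixed lists, 5 lay above and 5 below the central 95%.

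The comparison of the 3 h array with the adrenalectomized array addressed the early response to the hormone. Many genes known as direct targets of the glucocorticoid receptor were much higher 3 h after cortisol, among them Ddit4 and Sesn1, which encode inhibitors of growth signalling through mTOR. The metallothionein genes Mt1 and Mt2, the clock gene Per1, the chaperone gene Fkbp5 and Nfkbia, which encodes an inhibitor of inflammatory signalling, were also higher. Genes of slow fibres, such as the slow myosin and troponin genes, were several-fold lower, while genes of fast fibres differed little. Keratin and other genes of epidermis and hair were higher on the same array.

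Among 6168 genes compared, 115 were at least 2-fold higher and 72 at least 2-fold lower, 3.03% in all, and 137 of the 187 were measured above the floor on both arrays. Without the members of the epidermis, hepatocyte, slow fibre, fast fibre and lymphocyte lists, 89 were higher and 59 lower. Under scaling to ribosomal protein probe sets the split changed from 61.5% higher to 39.4% higher (82 higher and 126 lower), with the all-gene median at -0.23. Tiparp, a target gene of the aryl hydrocarbon receptor, had a signal of 2688 at 3 h and 173 after adrenalectomy alone, a 15.5-fold difference. Ddit4 was 12.6-fold higher, with 4250.3 against 339. The transcription factor gene Sox4 was 7.88-fold higher, Mt2 6.52-fold and Pag1, an adaptor of Src kinases, 6.24-fold. Krt10 (14.6-fold), Krt71 (7.98-fold) and S100a3 (6.94-fold), which are genes of epidermis and hair, completed the 8 measured genes named as highest. The junction gene Dsp was at least 17.2-fold higher, the hair keratin-associated gene Krtap8-1 at least 11.5-fold and the hair root sheath gene Krt27 at least 9.96-fold. The transcription factor genes Zbtb17 and Lef1 were 4.18-fold and 4.03-fold lower, and Lef1 had a log2 ratio of -0.95 when all its probe sets were averaged. Tyk2 was at least 3.55-fold lower, St3gal4 at least 3.11-fold and Sirpa at least 2.71-fold.

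Glucocorticoid-induced genes had a median log2 ratio of 0.69 over 28 members at 3 h (percentile 100), and 12 of the 28 were at least 2-fold higher. Fkbp5 was 4.74-fold higher (3771 against 796), Cebpd 4.19-fold, Nfkbia 3.86-fold, Gadd45g 3.70-fold and Mt1 3.47-fold. Per1 was 3.22-fold higher, Errfi1 2.51-fold, Sesn1 2.47-fold and Cebpb 2.05-fold, and Map3k6 was at least 7.58-fold higher. Cdkn1a, a cell cycle inhibitor gene, was 1.67-fold higher and Sgk1 1.55-fold. The myostatin gene Mstn had a log2 ratio of 0.56 and Pdk4 one of 0.32. Tsc22d3 was 1.65-fold lower and the receptor gene Nr3c1 1.58-fold lower. Glul, which encodes glutamine synthetase, differed by a log2 ratio of -0.03. Immediate early genes had a median of 0.31 over 15 members (percentile 100), which was 0.10 under scaling to ribosomal protein probe sets, with Zfp36, which destabilizes cytokine messengers, 2.23-fold higher and the nuclear receptor gene Nr4a1 2.03-fold higher. Amino acid metabolism genes had a median of -0.06, but the amino acid transporter gene Slc7a8 was 3.80-fold higher.

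**Figure D1:**
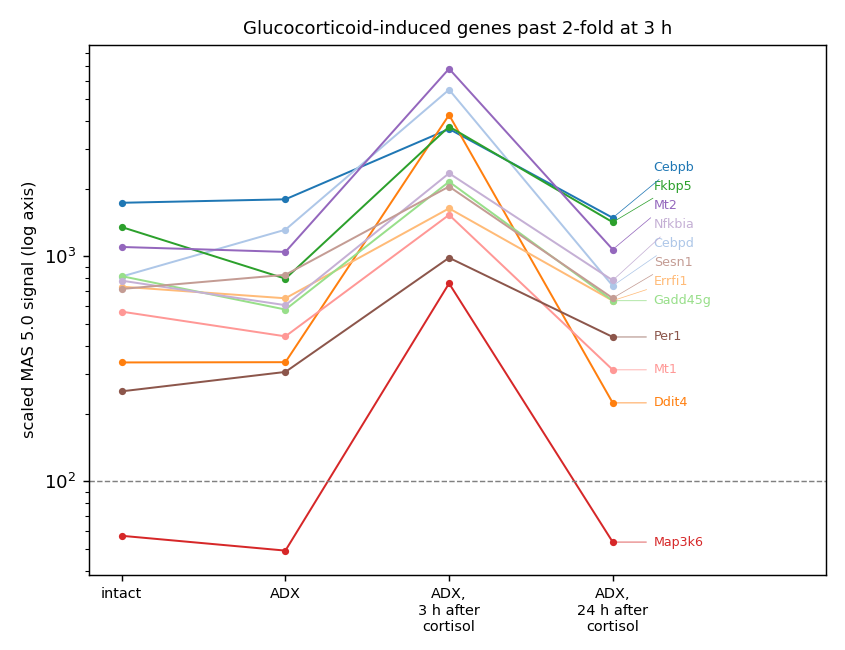
Scaled MAS 5.0 signal (log axis, arbitrary units) of the 12 glucocorticoid-induced genes that were at least 2-fold higher at 3 h, 1 line per gene over the 4 arrays, with the floor of 100 as a dashed line and 1 array per point. Ddit4 stood at 338 on the intact array, 339 after adrenalectomy, 4250.3 at 3 h and 223 at 24 h.

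Slow fibre genes had a median log2 ratio of -1.71 at 3 h, below all 10000 matched lists, and 8 of the 12 were at least 2-fold lower. Tnnt1, Tnni1 and Tnnc1, which encode the slow troponins, were 4.11-fold, 3.98-fold and 3.76-fold lower. The log2 ratio of Tnnt1 ranged from -2.25 to -1.57 over the alternatives. The slow myosin heavy chain gene Myh7 was 4.02-fold lower (2342 against 9419.7), the calcium pump gene Atp2a2 4.06-fold and the slow tropomyosin gene Tpm3 3.85-fold. Myl2 was 2.83-fold lower, Myl3 2.66-fold and the myoglobin gene Mb 1.45-fold. Fast fibre genes had a median of -0.05 over 15 members, with none past 1.5-fold, and Myh4 read 34919 after adrenalectomy and 33149 at 3 h. The highest deposited signals on these arrays were 36363 and 35938. Myh4 thus lay near the top of the range, and whether differences there were compressed was not tested. Genes enriched in the soleus, the slow muscle beside the gastrocnemius, but outside the slow fibre list were an added list and had a median of -0.22 over 10 members (percentile 0.27). None of the 10 passed 1.5-fold, and Actn2 was 1.46-fold and Fabp3 1.33-fold lower. All 10 soleus-enriched members reached the floor on the intact array and 4 belonged to another list too.

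**Figure D2:**
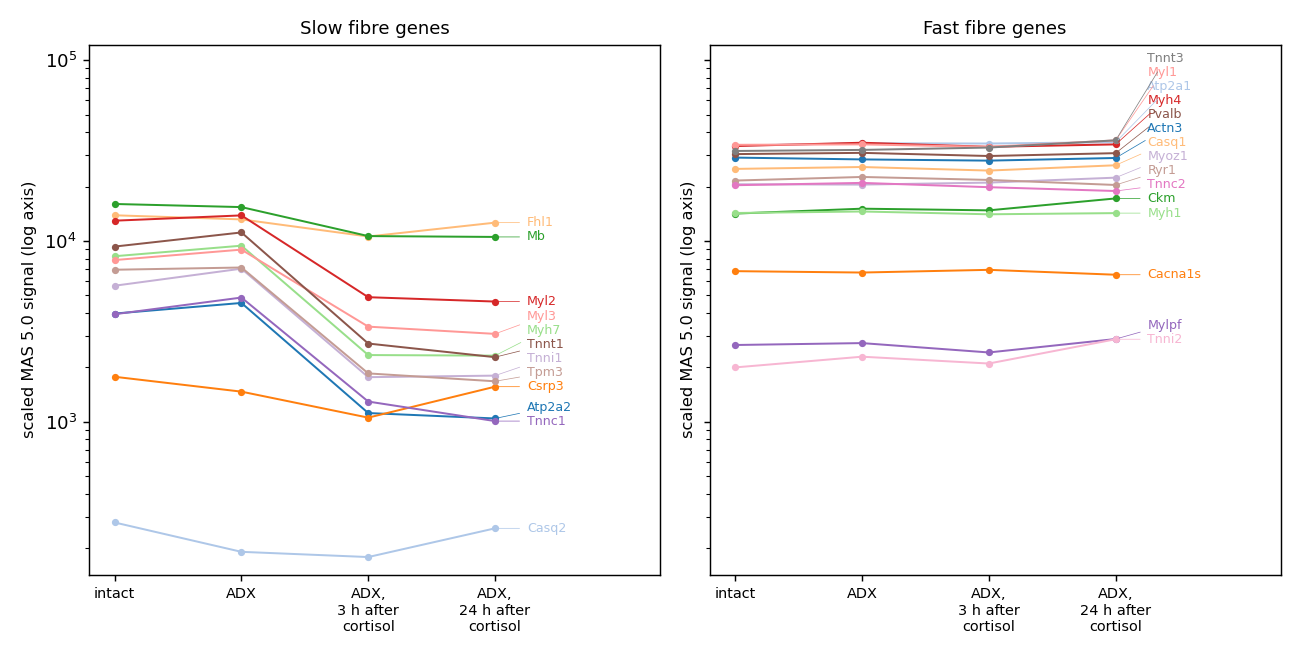
Scaled MAS 5.0 signal (log axis, arbitrary units) of 12 slow fibre genes and 15 fast fibre genes, 1 line per gene over the 4 arrays and 1 array per point. Myh7 was at 8238, 9419.7, 2342 and 2325 in the order intact, adrenalectomized, 3 h and 24 h, and Myh4 at 33475, 34919, 33149 and 34187.

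Epidermis and hair follicle markers, a list added because such genes were seen to be higher, had a median of 1.63 over 32 members at 3 h, and 26 of the 32 were at least 2-fold higher. Of its 38 members on the array, 19 reached the floor on the intact array, 19 on the adrenalectomized array and 32 at 3 h. The basal keratin genes Krt5, Krt14 and Krt15 stayed below the floor on all 4 arrays. Hepatocyte markers had a median of -0.64 over 19 members, with Serpina1e 2.80-fold, Serpina1b 2.44-fold, Alb 2.43-fold and Mup3 2.11-fold lower.

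The medians of the extracellular matrix, macrophage, interferon and inflammatory mediator lists were negative at 3 h, with members of several of them going both ways. Extracellular matrix genes had a median of -0.18 over 30 members (percentile 0.010), with the protease inhibitor gene Timp1 2.13-fold lower, Fn1 1.65-fold and Col6a2 1.51-fold. Against intact mice the matrix median at 3 h was 0.03 (percentile 91.2), which became negative under scaling to ribosomal protein probe sets, and the macrophage median was -0.14 (percentile 4.54). Macrophage markers had a median of -0.36 over 14 members (percentile 0.010), and none passed 2-fold. Tyrobp was 1.60-fold, Mrc1 1.49-fold and the growth factor receptor gene Csf1r 1.45-fold lower, while Fcgr3 was at least 1.59-fold higher. Interferon response and antigen presentation genes had a median of -0.24 over 17 members (percentile 0.42), and went both ways. The member with the largest ratio was Isg15, an interferon-induced ubiquitin-like gene, at 1.79-fold higher, while the interferon-induced GTPase genes Iigp1, Gbp2 and Gbp3 were 1.70-fold, 1.60-fold and 1.55-fold lower. The antigen presentation genes H2-D1, H2-K1 and B2m had log2 ratios of 0.24, 0.18 and 0.17, the last 2 of which became negative under scaling to ribosomal protein probe sets. Inflammatory mediators had a median of -0.32 over 6 members (percentile 2.31), with the chemokine gene Cxcl12 1.59-fold lower.

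Fatty acid uptake and oxidation genes had a median of -0.15 over 26 members at 3 h (percentile 0.010), yet the lipid-sensing receptor gene Ppara was 2.29-fold and the mitochondrial uncoupler gene Ucp3 1.66-fold higher. The coactivator gene Ppargc1a was at least 1.87-fold lower. Insulin-like growth factor and myogenic regulation genes had a median of -0.12 over 23 members (percentile 3.61), with Myod1, which drives muscle differentiation, 2.29-fold lower, the insulin receptor substrate gene Irs1 1.52-fold and Myf6 1.45-fold. Muscle atrophy and autophagy genes had a median within 0.01 of 0 over 16 members, and Foxo3, a transcription factor gene of muscle wasting, was 1.67-fold higher. The atrophy ubiquitin ligase genes Fbxo32 and Trim63 had no probe set with a single gene symbol. Circadian clock genes had a median of -0.13 over 14 members, with the repressor genes Bhlhe40 and Nr1d1 2.12-fold and 2.07-fold lower and Dbp, a clock output gene, 1.62-fold lower. Endothelial markers had a median of -0.13 over 11 members and went both ways, with Kdr 1.99-fold and Tek 1.64-fold lower and Flt1 1.59-fold and Tie1 1.55-fold higher.

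Ribosomal proteins had a median of 0.12 over 24 members (percentile 100), which became -0.08 when the arrays were scaled to these same probe sets. Gfap, among the Schwann cell and nerve markers with their median of -0.04, was 2.15-fold higher. The other medians at 3 h were -0.19 for polyamine synthesis genes, -0.12 for satellite and smooth muscle markers, -0.05 for glucocorticoid receptor and steroid metabolism genes (positive when all probe sets of a gene were averaged), -0.03 for glycolysis and glycogen genes and -0.02 for heat shock proteins. B and T lymphocyte markers had a median of 0.15, erythroid markers 0.10, oxidative phosphorylation genes 0.03, cholesterol and fatty acid synthesis genes 0.01 and adipocyte markers 0.01, and all of these became negative under scaling to ribosomal protein probe sets. Proteasome subunits had a median within 0.01 of 0, and neutrophil markers one of -0.02 whose sign turned under median and loess scaling. In all, 3 of the 28 fixed lists lay above and 6 below the central 95%.

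**Figure D3:**
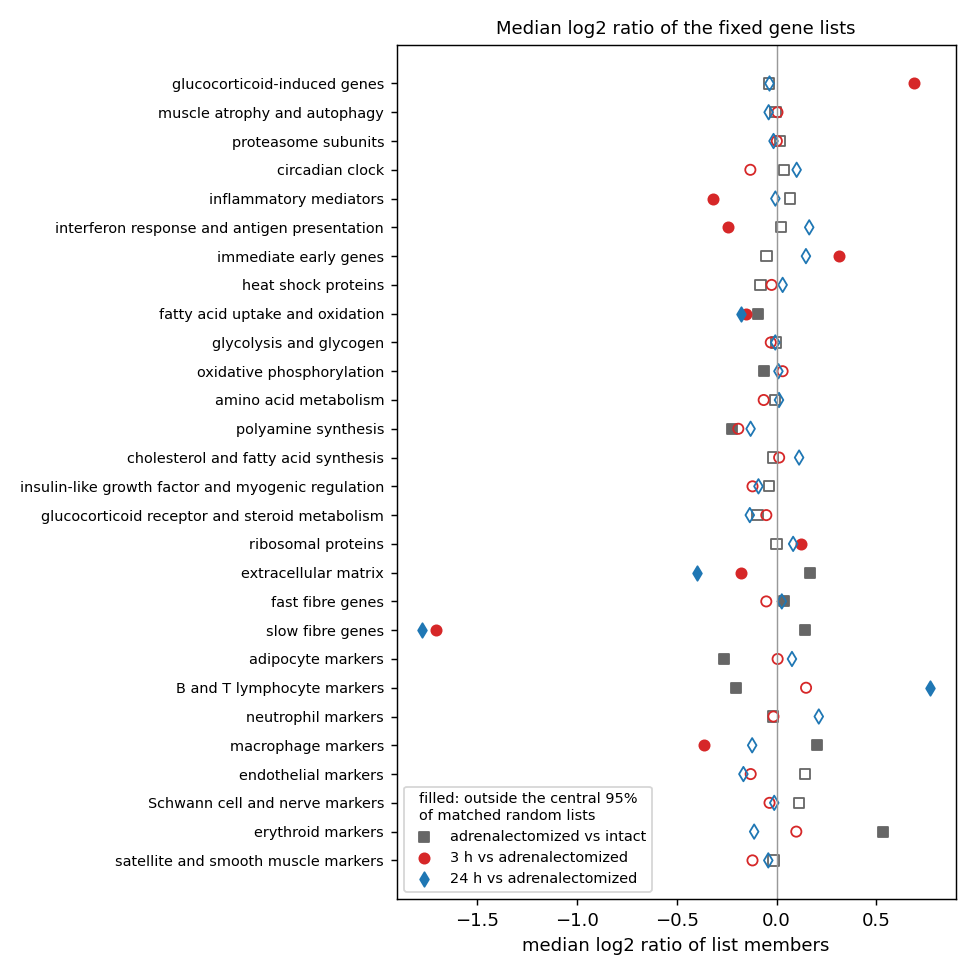
Median log2 ratio (horizontal axis) of the 28 fixed gene lists in the 3 main comparisons, 1 point per list and comparison, filled where the median lay outside the central 95% of matched random lists. Slow fibre genes stood at -1.71 at 3 h and -1.77 at 24 h and glucocorticoid-induced genes at 0.69 at 3 h, while several medians near 0 changed sign under scaling to ribosomal protein probe sets.

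The comparison of the 24 h array with the adrenalectomized array addressed the later response. At 24 h most glucocorticoid-induced genes were near the level of the adrenalectomized array. Pdk4, whose product inhibits the mitochondrial enzyme pyruvate dehydrogenase, was lower. Slow fibre genes were as low as at 3 h. The median of the extracellular matrix list was lower, with collagen genes among its lower members. The median of B and T lymphocyte markers was higher than in adrenalectomized mice, and so was the immunoglobulin gene Igkv6-23.

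Among 6228 genes compared, 79 were at least 2-fold higher and 66 at least 2-fold lower, 2.33% in all, and 82 of the 145 were measured above the floor on both arrays. Without the members of the epidermis, hepatocyte, slow fibre, fast fibre and lymphocyte lists, 65 were higher and 52 lower. The share of higher genes was 54.5%, and 18.4% (38 higher and 169 lower) under scaling to ribosomal protein probe sets, where the all-gene median was -0.30. Ada, an enzyme gene of purine breakdown, was 3.08-fold higher, with 672 at 24 h and 218 after adrenalectomy. Tex2 was 3.08-fold higher, Krt10 3.03-fold, the mitochondrial genes Atad3a 2.95-fold and Tmem70 2.84-fold, the calcium channel subunit gene Cacnb2 2.94-fold and Traip 2.70-fold. Hcrt was at least 4.21-fold and Otog at least 3.76-fold higher. Tnnt1 and Tnnc1 were 4.89-fold and 4.82-fold lower, and the liver protease inhibitor gene Serpina1b was 4.82-fold lower. Over the alternatives the log2 ratio of Tnnt1 ranged from -2.60 to -1.11. Against intact mice its range at 24 h was -2.21 to -0.89, past 2-fold under 9 of 10 alternatives. Atp2a2 was 4.35-fold lower, Tpm3 4.25-fold, Myh7 4.05-fold, Zbtb17 4.04-fold and Lef1 3.91-fold. The imprinted noncoding gene Meg3 was at least 5.09-fold lower, Get4 at least 3.99-fold and Myt1l at least 3.40-fold.

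B and T lymphocyte markers had a median of 0.77 over 10 members at 24 h (percentile 100), and 5 of the 10 were at least 2-fold higher. The B cell receptor genes Cd79a and Cd79b were 4.08-fold and at least 2.62-fold higher, Cd4 was 2.65-fold, Cd52 2.29-fold and Cd22 at least 2.04-fold higher. Against 3 h and against intact mice, Cd22 at 24 h was past 2-fold under only 5 of 9 alternatives. Igkv6-23 was at least 13.3-fold higher, by a probe set with a suffix of shared or relaxed probes. Of the 17 lymphocyte markers on the array, 8 reached the floor on the intact array, and the median against intact mice was 0.37. Whether the pools held different amounts of lymphoid tissue was not tested. The chemokine gene Ccl8 was 2.19-fold higher, within a list of inflammatory mediators whose median was -0.01 and turned positive when all probe sets of a gene were averaged.

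Extracellular matrix genes had a median of -0.40 over 30 members at 24 h, below all 10000 matched lists, with 10 members past 1.5-fold lower and none past 1.5-fold higher. Lox was 1.83-fold lower, Col5a2 1.76-fold, Col1a1 1.76-fold and Col3a1 1.68-fold. Slow fibre genes had a median of -1.77, with 8 of the 12 at least 2-fold lower, and soleus-enriched genes one of -0.19 (percentile 1.08, and 2.72 among random lists without matching). Fatty acid uptake and oxidation genes had a median of -0.18 over 26 members (percentile 0.010), and Pdk4 in that list was 3.07-fold lower, with 2425 against 7443. Hepatocyte markers had a median of -0.31 over 20 members, with 6 at least 2-fold lower. Of their 31 members on the array, 21 reached the floor on the intact array. Epidermis and hair follicle markers had a median of 0.66 over 28 members, with 9 at least 2-fold higher.

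**Figure D4:**
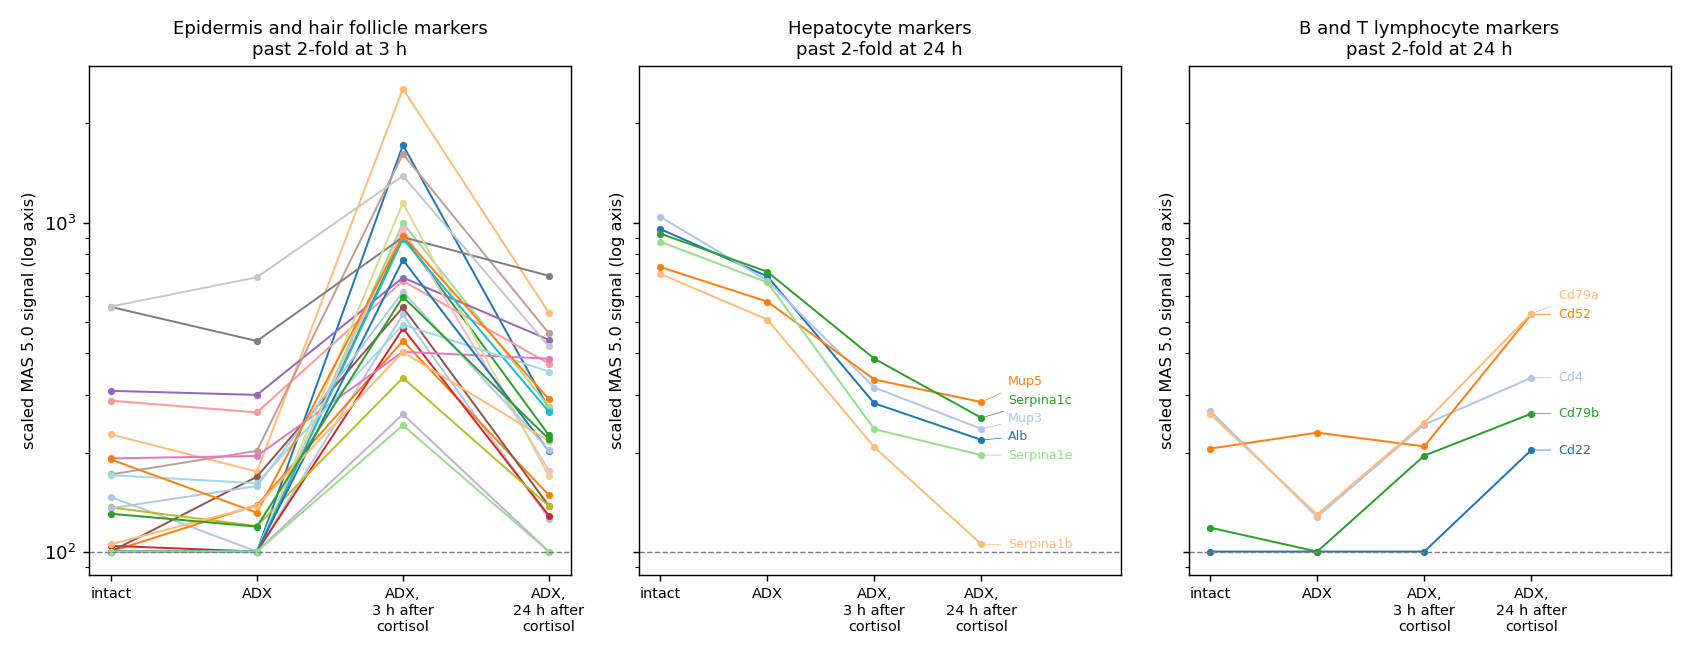
Scaled MAS 5.0 signal (log axis, arbitrary units) of list members drawn because they passed 2-fold against adrenalectomized mice: 26 of 32 epidermis and hair follicle markers at 3 h, 6 of 20 hepatocyte markers at 24 h and 5 of 10 lymphocyte markers at 24 h, 1 line per gene over the 4 arrays and 1 array per point, with values below the floor of 100 drawn at the floor (dashed line). Alb stood at 956, 686, 282 and 218 in the order intact, adrenalectomized, 3 h and 24 h, and Krt10 at 227, 175, 2549 and 531.

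Glucocorticoid-induced genes had a median of -0.04 over 27 members at 24 h (percentile 24.7), with Fkbp5 1.78-fold higher and Cebpd 1.78-fold lower. Mt2 read 1072 at 24 h and 1047 after adrenalectomy. Tsc22d3, Nr3c1, Sgk1, Cdkn1a, Mt1, Per1, Glul and Mstn each differed by less than 1.5-fold. Dbp was 2.10-fold higher. Slc2a1, which encodes a glucose transporter, was at least 2.08-fold lower, and Atp5g1, which encodes a subunit of the ATP synthase, was 2.05-fold higher but past 2-fold under only 5 of 10 alternatives.

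The other lists lay inside the central 95% at 24 h. Interferon response and antigen presentation genes had a median of 0.16, immediate early genes 0.15, neutrophil markers 0.21, circadian clock genes 0.10, cholesterol and fatty acid synthesis genes 0.11, ribosomal proteins 0.08, adipocyte markers 0.08, fast fibre genes 0.03 and heat shock proteins 0.03, and all of these became negative under scaling to ribosomal protein probe sets. The medians were 0.01 for amino acid metabolism genes and 0.01 for oxidative phosphorylation genes, and both turned negative under that scaling too. Endothelial markers had a median of -0.17, glucocorticoid receptor and steroid metabolism genes -0.13, polyamine synthesis genes -0.13, macrophage markers -0.12, erythroid markers -0.11 and insulin-like growth factor and myogenic regulation genes -0.09. Satellite and smooth muscle markers and muscle atrophy and autophagy genes each had a median of -0.04, the former turning positive with a floor of 50, and Schwann cell and nerve markers one of -0.01. Proteasome subunits (-0.02) and glycolysis and glycogen genes (-0.01) turned positive under quantile normalization. Of the 28 fixed lists, 1 lay above and 3 below the central 95%.

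The course after the injection was read from the 24 h array against the 3 h array. Ddit4 was 19.0-fold lower at 24 h than at 3 h, Sox4 14.7-fold, Tiparp 10.6-fold and Cebpd 7.44-fold. Mt2 was 6.36-fold lower, Mt1 4.88-fold, Slc7a8 3.88-fold, Pdk4 3.84-fold, Fkbp5 2.66-fold and Per1 2.25-fold. Dbp was 3.41-fold higher, Nr1d1 2.79-fold, Bhlhe40 2.55-fold and Myod1 2.15-fold, and Tmem70, Tmem129 and the leukocyte gene Lcp1 were 3.90-fold, 3.55-fold and 3.00-fold higher. Of 6229 genes, 82 were at least 2-fold higher and 122 lower, or 78 and 102 without the members of the 5 lists named above. The share of higher genes was 40.2%, and it was 25.5% (51 higher, 149 lower) under ribosomal and 29.9% (60 higher, 141 lower) under loess scaling. Glucocorticoid-induced genes had a median of -1.03, with 15 of 28 at least 2-fold lower, and slow fibre genes one of -0.05, which turned positive without probe sets of shared probes. Interferon response and antigen presentation genes had a median of 0.31 (percentile 99.8), with the immunoproteasome gene Psmb9 2.09-fold higher but past 2-fold under only 6 of 10 alternatives, and lymphocyte markers one of 0.40 (percentile 99.7). Extracellular matrix genes had a median of -0.29 and epidermis and hair follicle markers one of -1.50.

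Of the 115 genes at least 2-fold higher at 3 h, 26 were still at least 2-fold higher at 24 h, 72 were within 1.5-fold of the adrenalectomized array and none was 2-fold lower. Their median log2 ratio was 1.39 at 3 h and 0.23 at 24 h. Of the 72 lower genes, 23 were still at least 2-fold lower at 24 h, and the median was -1.19 at 3 h and -0.45 at 24 h. Among the 26 genes higher at both times, 9 were within 1.5-fold of the intact level at both times, so that the adrenalectomized array was the one that differed; Dbnl, with 331, 121, 319 and 306 in the order of the groups, was such a gene, chosen after its values were seen. Another 10 were at least 2-fold above intact at both times. They were the keratin genes Krt10, Krt25, Krt27 and Krt71, with Dsp, Krtdap, Ly6d, Perp, Glra1 and Traip. Among the 23 genes lower at both times, 14 were also at least 2-fold below intact at both times. They were the slow fibre genes Atp2a2, Myh7, Myl2, Myl3, Tnnc1, Tnni1, Tnnt1 and Tpm3, and the hepatocyte markers Alb, Mup3, Serpina1b and Serpina1e. The others were Zbtb17 and Ptpru, the last chosen after its values were seen.

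Over the 5452 genes at or above the floor on all 4 arrays, the log2 ratios at 3 h and at 24 h against the adrenalectomized array had a Pearson r of 0.42 and a Spearman rho of 0.39 across genes, which are not independent replicates. Simulated unchanged arrays that shared the same adrenalectomized array gave r 0.50. The covariance was 0.0529, against 0.0242 in the simulation. The simulated noise came from adrenalectomized against intact, the most alike pair of arrays, so simulated covariances and overlaps may be too low. Without a shared array, 3 h against adrenalectomized and 24 h against intact gave r 0.15 and rho 0.09, with a covariance of 0.0192. Among these genes 12 were at least 2-fold higher in both comparisons with the adrenalectomized array, of 68 and 36, where independent lists would share 0.45 and the simulation gave 0.07. Another 18 were lower in both, of 58 and 38, against 0.40 and 0.04. With no shared array, 5 were higher in both and 16 lower in both, against 0.39 and 0.43 for independent lists. The slow fibre genes and hepatocyte markers named just above were among the 18 and among the 16. The ratio of adrenalectomized to intact had r -0.35 with the 3 h ratio and r -0.38 with the 24 h ratio, and the simulation gave -0.50 for each. The covariances were -0.034 and -0.034, against -0.024 and -0.024 in the simulation.

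Against intact mice, the injected groups showed how far each array lay from normal muscle. At 3 h Ddit4 was 12.6-fold, Krt10 11.2-fold, Sox4 10.3-fold, Krt71 9.41-fold, Cebpd 6.77-fold, Mt2 6.20-fold, Per1 3.92-fold, Fkbp5 2.79-fold and Mt1 2.69-fold above intact. Tpm3 was 3.74-fold, Serpina1e 3.71-fold, Atp2a2 3.55-fold and Myh7 3.52-fold below intact. Of 6162 genes, 113 were at least 2-fold higher and 64 lower, 63.8% higher, or 88 and 47 without the members of the 5 lists, and under scaling to ribosomal protein probe sets 94 were higher and 81 lower (53.7%). Glucocorticoid-induced genes had a median of 0.73, immediate early genes 0.35, fatty acid uptake and oxidation genes -0.22 and slow fibre genes -1.50. Hepatocyte markers had a median of -0.80 and epidermis and hair follicle markers one of 1.89.

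At 24 h the glucocorticoid-induced genes had a median of -0.14 against intact mice (percentile 1.13), and Fkbp5 read 1418 where intact mice had 1349. Pdk4 was 2.66-fold lower and Dbp 2.49-fold higher than in intact mice. Igkv6-23 was 3.24-fold, Pdc 3.13-fold, the Mediator subunit gene Med27 2.81-fold and Tmem70 2.78-fold higher. Serpina1b was 6.64-fold, Serpina1e 4.45-fold, Mup3 4.41-fold and Alb 4.38-fold lower. Of 6219 genes, 69 were at least 2-fold higher and 63 lower, 52.3% higher, or 55 and 48 without the members of the 5 lists. The share of higher genes was 24.6% (31 higher, 95 lower) under ribosomal scaling, with the all-gene median at -0.16, and 41.0% (50 higher, 72 lower) under quantile and 40.8% (49 higher, 71 lower) under loess normalization. Slow fibre genes had a median of -1.57, fatty acid uptake and oxidation genes -0.26, extracellular matrix genes -0.25, insulin-like growth factor and myogenic regulation genes -0.16, erythroid markers 0.42 and hepatocyte markers -0.76.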

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

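Probe sets with no single gene symbol entered no comparison. They were examined here for signals above both arrays of mice without an injection, and the form of this check was chosen after the data had been seen. Of 1589 such probe sets, 12 on the 3 h array were at least 2-fold above both the intact and the adrenalectomized array. On the 24 h array the number was also 12. They drew attention because they are signals in data that the comparisons did not use. The annotation gave several symbols for 4 of the 12 at 3 h and for 3 of the 12 at 24 h, and no symbol for the other 8 and 9. No explanation of them was tested.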

How the results depend on the processing

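The restriction to genes of at least 500 on the brighter array, the restriction to genes at or above the floor on both arrays and the omission of 5 lists with 114 members were chosen after seeing the data. The other alternatives were fixed in advance. No paired analysis was possible because each group had 1 array, and for the same reason leaving out 1 array at a time was not possible.

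Counts are given in the order adrenalectomized against intact higher and lower, 3 h against adrenalectomized higher and lower, 24 h against adrenalectomized higher and lower, then the totals of 24 h against 3 h, 24 h against intact and 3 h against intact. The reported counts were 21, 23, 115, 72, 79, 66, 204, 132 and 177. With a floor of 50 they were 101, 92, 214, 157, 196, 158, 411, 348 and 370, and with a floor of 200 they were 4, 7, 68, 34, 17, 26, 89, 51 and 101. With log2(signal + 32) and no floor they were 93, 104, 198, 136, 208, 145, 373, 330 and 353. These shifts follow from the construction, since a lower floor lets dim genes pass and a higher floor shrinks their ratios. At 1.5-fold the counts were 163, 137, 313, 293, 342, 281, 725, 621 and 613, and at 3-fold 0, 6, 47, 10, 9, 21, 46, 20 and 57, by the construction of the size rule. Among genes of at least 500 on the brighter array they were 1, 3, 62, 27, 12, 22, 81, 37 and 86, as fewer genes entered. Among genes at or above the floor on both arrays, 13 were lower in adrenalectomized against intact mice, 43 higher and 39 lower at 24 h against adrenalectomized, and 83 passed in 24 h against intact, again with fewer genes. Scaling to ribosomal protein probe sets gave 38 higher genes in adrenalectomized against intact mice, 126 lower at 3 h, and 38 higher and 169 lower at 24 h. This scaling moved the all-gene median to 0.13, -0.23 and -0.30. Its factor was the geometric mean of all ribosomal protein probe sets, with no floor. Of 32 ribosomal protein genes, 23, 23, 24 and 25 reached the floor on the arrays in the order of the groups. Under the reported scaling the ribosomal protein list had medians of 0.0001, 0.12 and 0.08 in the main comparisons. Probe sets below the floor thus helped to set the factor, and the cause was not tested further. The other counts under the alternatives stayed within 1.5 times the reported ones.

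A change of sign was found for 4 list medians that had lain outside the central 95%. Scaling to ribosomal protein probe sets gave 0.030 for fatty acid uptake and oxidation genes and 0.060 for oxidative phosphorylation genes in adrenalectomized against intact mice, and -0.081 for ribosomal proteins at 3 h, where the scaling moves all genes by construction. Without probe sets of shared probes the hepatocyte median of 24 h against 3 h was 0.038, and the cause was not tested. Among all list medians, 1569 of the alternative values stayed within 1 SD of the random medians, 287 moved further and 157 of these 287 were under ribosomal scaling.

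The slow fibre median ranged from -1.91 to -1.46 at 3 h and from -2.08 to -1.33 at 24 h over the alternatives. The glucocorticoid-induced median at 3 h ranged from 0.48 to 0.73, the lymphocyte median at 24 h from 0.45 to 0.95 and the extracellular matrix median at 24 h from -0.70 to -0.35. The epidermis and hair follicle median at 3 h ranged from 1.31 to 1.68 and the hepatocyte median from -0.82 to -0.53 at 3 h, from -0.83 to -0.31 at 24 h against adrenalectomized and from -1.12 to -0.50 at 24 h against intact. At 3 h the immediate early median ranged from 0.10 to 0.37, the interferon median from -0.45 to -0.07 and the inflammatory mediator median from -0.50 to -0.07. The correlation of the 3 h and 24 h ratios ranged from 0.40 to 0.45, and the one without a shared array from 0.13 to 0.16. The correlations with the ratio of adrenalectomized to intact ranged from -0.38 to -0.35 for 3 h and from -0.39 to -0.35 for 24 h.

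With random lists without matching, 3 percentiles came inside the central 95%: 95.4 for slow fibre genes and 63.8 for fast fibre genes in adrenalectomized against intact mice, and 2.72 for soleus-enriched genes at 24 h. Another 2 went outside it, those of inflammatory mediators in 24 h against 3 h and of interferon response genes in 24 h against intact. For single named genes, 7702 values stayed within the probe set error and 419 moved further, 213 of them under the floor of 200. Of the named genes past 2-fold, 380 of 393 alternative values were still past it at 3 h, 327 of 352 at 24 h and 211 of 236 in adrenalectomized against intact mice, and dim genes such as Pmm1, Cacnb2, Otog, Trh and Lsm2 lost it under the floor of 200. With all probe sets averaged, Lef1 came to -0.95 at 3 h and -0.76 at 24 h and Dynll2 to -0.72, and without probe sets of shared probes Atad3a and Pdc were below the floor on both arrays. Atp5g1 at 24 h was past 2-fold under 5 of 10 alternatives, with a lowest log2 ratio of 0.62, Gfap at 3 h under 6, Psmb9 in 24 h against 3 h under 6, Ccl8 at 24 h under 7, and Cd4 and Cd79a in adrenalectomized against intact mice under 7 each. By mean signal, 23 of 1691 genes under 300 passed 2-fold on both arrays in adrenalectomized against intact mice, 3 of 2452 at 300 to 1000 and 2 of 1517 above 1000. At 3 h against adrenalectomized these numbers were 59 of 1694, 51 of 2438 and 27 of 1522.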

Other observations

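The tests of the 3 patterns weighed here were all chosen after the patterns had been seen, and the genes followed over all 4 arrays were chosen after their values were seen.

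Clock genes moved apart from each other over the 4 arrays. In the order intact, adrenalectomized, 3 h and 24 h, Per1 read 251, 306, 986 and 438, Nr1d1 read 2396, 1981, 958 and 2670.2, Bhlhe40 read 1383, 1359, 641 and 1636, and Dbp read 340.4, 403, 249 and 847. Arntl, which encodes the activator of the clock, read 553, 438, 473 and 385. The labels gave no time of day, so hours after injection and hour of the day were not separated in these data.

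Several genes had their lowest signal on the adrenalectomized array. Otog read 382, 74.8, 274 and 376, Hcrt read 308, 81.9, 317 and 421, Tex2 read 382, 112, 295 and 346, and Ido1, an enzyme gene of tryptophan breakdown, read 209.9, 24.1, 207 and 269. Gpcpd1, a phosphodiesterase gene tied to muscle growth, was brighter, at 2295, 1191, 2627 and 2692. Igkv6-23 read 411, 69.7, 468 and 1332, and the antibody joining chain gene Jchain read 157, 81.4, 206 and 341. Lef1 had its highest signal there, at 185, 457, 113 and 117. No explanation of these profiles was tested.

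Slow fibre genes were lower on both arrays of injected mice, to a median log2 ratio of -1.71 at 3 h. The scaling of the arrays was argued against, since the value nearest to 0 over 6 scalings and both times was -1.684. A smaller share of slow muscle in the pools of injected mice, for example less soleus left on the gastrocnemius, is a candidate explanation: the soleus-enriched genes outside the slow fibre list had negative medians at both times, with percentiles up to 1.08, though the 24 h percentile was 2.72 without matching and 4 of the 10 genes belong to another list. Their medians of -0.22 and -0.19 were far smaller than the slow fibre medians, and none of the 10 passed 1.5-fold. A lower level of slow fibre transcripts after the injection may also give the value of -1.706, and with 1 pool per group it cannot be told apart from the dissection.

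Epidermis and hair follicle genes were higher on the 3 h array and less so on the 24 h array; the brightest signals at 3 h were Krt10 at 2549, Dsp at 1719.9 and Krt71 at 1614, and 19 of 38 reached the floor in intact muscle. The scaling of the arrays was argued against, since the lowest 3 h median over 6 scalings was 1.422. Skin or hair in the pools of injected mice is a candidate explanation that the values leave open: the highest of the basal keratin genes Krt5, Krt14 and Krt15, which are abundant in epidermis, read 19.29 at 3 h, but these probe sets were below the floor on all 4 arrays, so nothing shows that they can detect their transcripts. Induction by the glucocorticoid in muscle was examined by the median share of the 3 h rise over adrenalectomized mice that was left at 24 h as a rise over intact mice, which was 0.1922 for 26 members and -0.023 for 12 glucocorticoid-induced genes and which leaves it open. With 1 pool per group these explanations cannot be told apart.

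Hepatocyte genes had a median log2 ratio of -0.76 in 24 h against intact, and negative medians in all 3 main comparisons. The members were uneven in 24 h against intact. Of 22 compared, 7 were at least 2-fold lower, 13 at least 1.5-fold lower and none 1.5-fold higher. The highest log2 ratio was 0.35. Cyp2e1 read 1601 on the intact array and 1742 on the 24 h array, 1.09-fold higher. The median of 24 h against 3 h was -0.23 and became 0.038 without probe sets of shared probes. A loss of signal common to dim probe sets along the fluidics modules was argued against. The 4345 other genes with intact signals of 100 to 1000 had a median log2 ratio of 0.03235 in 24 h against intact. That median follows scaling of every array to the same trimmed mean, and a module effect on fewer genes was not tested. Liver RNA in different shares in the pools is a candidate explanation that stays open: over 23 members the excess of intact over 24 h followed the excess of adrenalectomized over 3 h with r 0.7445, but a fall of every member by 1 factor from any cause would give 0.975. Mup3, Alb, Serpina1b, Ttr, Apoa2 and Apoa1 read 1041, 956, 698, 195, 171 and 138 on the intact array, where 21 of 31 members reached the floor. A lower level of these transcripts in muscle after adrenalectomy and injection may also give the medians below 0, the nearest to 0 being -0.3119, and with 1 pool per group it cannot be told apart from liver RNA.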
